A study of Homo sapiens with 4 samples.

How the data were processed

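m6A-seq was performed on wild-type H1 human embryonic stem cells with a commercial m6A antibody. The labels gave 2 input and 2 pull-down libraries of total RNA, and these 2 groups were taken from the sample titles. Nothing in the labels said whether replicates came from separate cultures. Per the submitters' processing notes, the tools included Trim Galore 0.6.7, HISAT2 2.2.1, SAMtools 1.6, MACS2 2.2.7.1, bedtools 2.30.0 and HOMER, with hg38 as the genome; their settings and order were not given in the sources used here. How reads with several alignments were treated was likewise not given.

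The authors deposited 1 set of 9900 peak positions, in base pairs on hg38, and a HOMER annotation of the same 9900 positions. Per the file name, the deposited set is an intersection of MACS2 peaks; what was intersected is not given in the sources used here. The deposited start and end coordinates, other than any count or signal, were the only measurement of each region, together with the deposited distance of its centre to the nearest start site, in base pairs. The Peak Score column of the deposited annotation was 0 and the strand was the same in every line, so neither was used. No region overlapped another and the smallest gap was 709 bp. Values per library, depths and RNA levels were not in these files. The precision of a share was therefore set by the number of regions or genes alone.

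Features were those HOMER gave the centre of each region: promoter, transcript end, coding exon, 5' UTR, 3' UTR, non-coding exon, intron or intergenic. A region was called exonic when its centre was in a coding, UTR or non-coding exon. Its host gene was found by matching the transcript in the annotation to a RefSeq gene table of GRCh38.p14; 8523 of 8585 such regions (99.3%) matched. Of the unmatched ones, 27 were exonic; in an alternative, 19 of these were given to the 1 protein-coding gene whose body held the centre, which added 18 genes. The start site that each distance implied lay within 1000 bp of a gene boundary of that table for 81.5% of 9775 regions, and within 2 bp for 64.9%.

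A member of a gene list was counted when it hosted at least 1 exonic region. Shares were compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 35 tests (20 lists and 15 families by symbol pattern). The threshold was an adjusted p of 0.05. The lists were fixed before the data were examined, every listed symbol matched the gene table, and a few genes belong to more than 1 list. The position of coding-exon regions was taken from the exon number and exon count of the annotation and compared with 10000 draws in which each exon of the same transcript was equally likely, two-sided. This test replaced planned ones that needed transcript models. Repeat classes at region centres were compared between narrow (up to 2 kb) and wide (over 5 kb) regions by Fisher's exact test.

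Not run here, because they need a genome sequence, transcript models or a peak score, were the tests of the DRACH motif, of distance to the stop codon, of long internal exons, of placement along transcripts and of a minimum overlap with exons, the matching on exonic length and the choice of the longest transcript, and the stricter set of peaks by caller score. Gene body length replaced exonic length. Distance to the 3' end was not tested since the strand of the gene could be derived for too few regions.

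Alternatives were a minimum width, merging of close regions, naming genes by the nearest start site, a background without olfactory receptors and keratins, and, chosen after seeing the data, regions up to 2 kb only, any overlap with the gene body, exons with transcript ends and promoters, a background of genes with a region, lists matched on gene body length in 20 bins, and variants of the last-exon and repeat tests. Naming by the nearest start site used all 9900 regions, exonic or not. It gave 5244 protein-coding genes with a region, against 2569 with an exonic one. The genes named were OTX2, TFAP2C and IGF2BP1, the 10 protein-coding genes with most exonic regions, and of each list up to 4 members with a region (most regions first, then most bases) and up to 3 without (in alphabetical order). Outside that rule, SOX17, PRDM1, NANOS3, POU5F1, NANOG, NANOGP1, METTL3, IGF2BP2, IGF2BP3, SLC2A14, KDM4B, SRP19 and the gene pairs at the ends of regions over 100 kb were chosen after their values were seen. A few genes that the rule takes are not reported here.

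The tests were first tried on simulated data. Of 150 simulated lists whose share was raised from 13 to 40%, 140 were recovered (93.3%) over 20056 genes, and 1 of 1550 unchanged lists was called. The raised lists were those of histone lysine methylation, WNT and ZNF genes (42, 36 and 509 members), 50 times each. No smaller list was raised and no share was lowered, so recovery is unknown for those cases. With 1761 simulated regions, a share of them moved to the last exon, the exon test recovered 50 of 50 sets and called 3 of 50 unchanged ones. Length-matched lists in which length alone set detection were called in 30 of 1750 cases. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.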

Results

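N6-methyladenosine (m6A), a methylated form of adenosine in RNA, was mapped by antibody pull-down and sequencing in wild-type H1 cells, an established line of human embryonic stem cells. There were 4 libraries, 2 of input RNA and 2 of RNA recovered with the m6A antibody. The deposited data were 9900 m6A regions on hg38, a MACS2 peak set described as intersected, with no height, score or value per library. The regions had a median width of 1527 bp (quartiles 1070 and 2835 bp), and 73 were over 100 kb. With 1 intersected set there was no replicate error to set beside a difference. The depth of each library was unknown and RNA levels were not in the files, so a gene without a region is not shown to lack m6A. All intervals are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only.

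OTX2 mRNA, IGF2BP1 and TFAP2C are named in the title of the series, which concerns an m6A-dependent effect of IGF2BP1 on OTX2 in germ cell fate. OTX2, a homeobox transcription factor of primed pluripotency and anterior neural development, held 1 m6A region. It lay at chromosome 14, positions 56800759 to 56802001 (1243 bp), inside the OTX2 gene (positions 56799905 to 56810479), with its start 854 bp from the lower-coordinate boundary of the gene and its centre 4287 bp downstream of an annotated OTX2 start site. That start site was at 56805667, inside the gene, if OTX2 runs toward lower coordinates, and at 56797093, outside it, otherwise. The region therefore lay toward the 3' end of the gene. HOMER annotated the centre as exon 2 of 2 of a non-coding OTX2 transcript. TFAP2C, a transcription factor of primordial germ cells, held no region within its gene (chromosome 20, positions 56629306 to 56639283). The nearest region, 845 bp of intergenic sequence at positions 56625164 to 56626008, was centred 3720 bp upstream of the TFAP2C start site. IGF2BP1, an m6A-binding protein, had no region within 5 kb of its gene (chromosome 17, positions 48996558 to 49056145). Its paralog IGF2BP3 held 1 region of 1098 bp at chromosome 7, positions 23414722 to 23415819, in intron 3 of 14. The 1 region near IGF2BP2 was intergenic. Whether the OTX2 region held a consensus m6A motif was not analysed here.

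**Figure D1:**
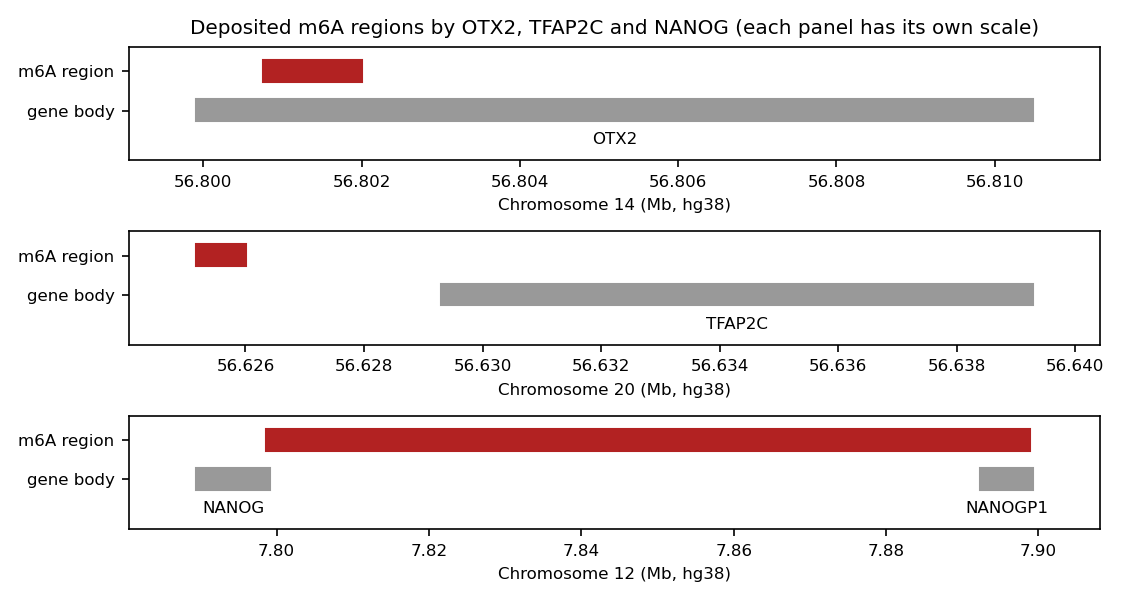
Positions of the deposited m6A regions (red) and gene bodies (grey) on hg38, in Mb along chromosomes 14, 20 and 12, each panel on its own scale. The OTX2 region lies inside the gene, the region by TFAP2C ends before the gene starts, and a region of 100260 bp runs from NANOG into NANOGP1.

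Introns held the largest share of region centres. Of the 9900 centres, 4967 were in introns (50.2%, interval 49.2 to 51.2%), 1913 in coding exons (19.3%, 18.6 to 20.1%), 1315 between genes (13.3%, 12.6 to 14.0%) and 705 in 3' UTRs (7.12%, 6.62 to 7.65%). Non-coding exons held 369 centres (3.73%), promoters 368 (3.72%), transcript ends 189 (1.91%) and 5' UTRs 74 (0.748%). There were 9.53 regions in 3' UTRs for each region in a 5' UTR. Intronic regions were wider, with a median of 2102 bp and 26.6% over 5 kb, against a median of 1350 bp and 0.680% over 5 kb in coding exons. Among the 6217 regions up to 2 kb, introns held 38.2%, coding exons 23.7% and 3' UTRs 9.64%. Coding exons, UTRs and non-coding exons together held 3061 centres (30.9%, 30.0 to 31.8%). These shares follow the centre of each region only, and no random placement along transcripts was run.

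Coding-exon regions lay mostly in the last exon of their transcript, and those of ZNF zinc finger genes did so more often than those of other genes. Of 1761 coding-exon regions in transcripts of 2 or more exons, 1008 were in the last exon (57.2%), where an equal chance for each exon gave 19.98%. Internal exons held 36.7% against 60.0%, and first exons 6.02% against 19.98%. Each of these 3 differences had a simulation p of 2.0e-04 over 10000 draws, two-sided, the smallest the draws can give. In ZNF genes, 241 of 269 regions were in the last exon (89.6%), against 767 of 1492 in other genes (51.4%), an odds ratio of 8.14 (Fisher's exact test, two-sided, p = 1.14e-35). APC, a component of the WNT pathway's destruction complex, held both of its regions in exon 16 of 16. LCOR, a nuclear receptor corepressor, had all 3 of its regions annotated to exon 8 of 8. On chromosome 10, 1 lay at 96955016 to 96956337 and the others between 96980888 and 96985507, so their transcripts may differ. Exon lengths did not enter the test, so a long last exon counts as 1 exon like any other. Only centres labelled coding exon entered, so centres in promoters and UTRs were left out. First exons kept a full chance all the same, so part of their low share may come from the labels. Exon numbers are those of the transcript the annotation named, so a last exon may be internal in a longer transcript. The TET2 regions, for example, were in exon 3 of 3 and in exon 11 of 11.

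**Figure D2:**
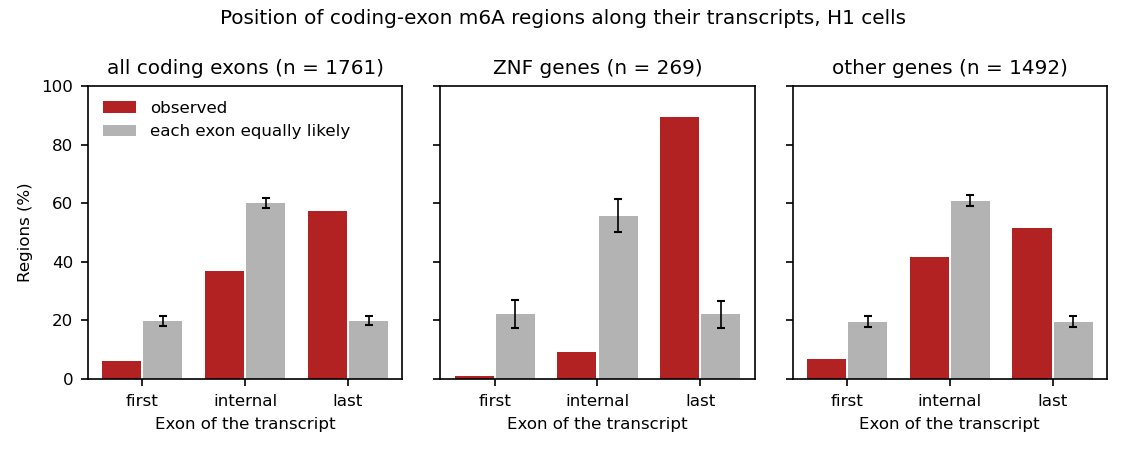
Share of coding-exon m6A regions (%, red bars) in first, internal and last exons, for all genes, ZNF genes and other genes, beside the share if each exon were equally likely (grey bars, with the central 95% of 10000 simulated draws). The last exon held 57.2% of regions over all genes, 89.6% in ZNF genes and 51.4% in other genes.

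Of 20056 protein-coding genes, 2569 (12.8%) held at least 1 exonic region. A single region was found in 2324 of them, 2 in 225 genes and 3 or more in 20 genes. PCLO, a presynaptic scaffold gene on chromosome 7, held the most, with 6, all in coding exons. FAT4, an atypical cadherin gene on chromosome 4, held 5, covering 11713 bp in exons 1, 5, 9 and 17 of 17. RGS3, a regulator of G protein signalling, held 4. PLEKHG4B, ALPK3, VTI1A, ONECUT2 and LCOR were among the genes with 3 each. The share of genes with an exonic region was 7.38% (6.59 to 8.23%) in the fifth of genes with the shortest gene body and 18.7% (17.5 to 19.9%) in the fifth with the longest. For any overlap of the gene body the shares were 14.2% and 50.1%.

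Genes of pluripotency, of the m6A machinery, of histone lysine methylation and of 2 signalling pathways held exonic regions more often than other genes. The other genes include any that are not transcribed in these cells. RNA levels and exon length were not held fixed, so either may account for such an excess. Of the 36 core and primed pluripotency genes, 13 held a region (36.1%, interval 20.8 to 53.8%), against 12.8% of other genes (odds ratio 3.86, adjusted Fisher's exact p = 0.00139). They included SALL4, a zinc finger factor of stem cells, with regions in exons 2 and 4 of 4, L1TD1, an RNA-binding protein of stem cells, with regions in exons 4 and 5 of 5, FOXO1, SOX11 and OTX2. CD9, CRIPTO and DNMT3B held none. POU5F1 had no region, and NANOG met only the 100260 bp region, which ran from chromosome 12, position 7798613, to 7898872 and was centred in an intron of SLC2A14. Of 28 genes of the m6A machinery, 11 held a region (39.3%, 21.5 to 59.4%; adjusted Fisher's exact p = 0.00153). Among them were ZC3H13, RBM15 and RBM15B of the methyltransferase complex and the reader PRRC2A. METTL3, the catalytic subunit, and the demethylase ALKBH5 held none. Histone lysine methyltransferases and demethylases had the highest share among the 20 lists, 21 of 42 genes (50%, 34.2 to 65.8%), with an odds ratio of 6.86 (adjusted Fisher's exact p = 4.23e-08). KMT5B, KMT2C, NSD1 and KMT2B each held 2 regions, and EHMT2, KDM1A and KDM1B none.

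WNT signalling genes held regions in 14 of 36 cases (38.9%, 23.1 to 56.5%; adjusted Fisher's exact p = 3.7e-04), among them APC, the Wnt receptors FZD7 and FZD5 and the ubiquitin ligase ZNRF3. CTNNB1, which encodes beta-catenin, held none. TGF-beta, NODAL and BMP signalling genes held them in 11 of 40 cases (27.5%, 14.6 to 43.9%; adjusted Fisher's exact p = 0.0289), including the receptors BMPR2 and ACVR2B, the ubiquitin ligase SMURF1 and the inhibitory SMAD6. Immediate early genes held them in 8 of 28 cases (28.6%, 13.2 to 48.7%; adjusted Fisher's exact p = 0.0407), including JUN, MCL1, IER2 and ZFP36. The immediate early difference of 15.8 percentage points did not pass without olfactory receptors and keratins in the background (15.4 points), with any overlap of the gene body (12.7) or with regions up to 2 kb (7.46; adjusted Fisher's exact p from 0.05002 to 0.314). JARID2 and OTX2 were among the pluripotency genes with a region, and JARID2 also belongs to the Polycomb list. Against the 6058 genes with a region in an exon or anywhere over the gene body, the histone lysine list was still higher (adjusted Fisher's exact p = 6.48e-04) and the other 5 lists did not pass the threshold (adjusted p from 0.0908 to 0.768), with differences of 22.7 percentage points for pluripotency (23.3 against all other genes), 31 for the m6A machinery (26.5), 27.7 for WNT (26.1), 24.3 for immediate early genes (15.8) and 7.62 for TGF-beta (14.7). When genes were named by the nearest start site, the m6A machinery, histone lysine, WNT and immediate early lists did not pass (adjusted Fisher's exact p from 0.113 to 0.157), with differences of 16.7, 12, 15.55 and 16.7 points, and the TGF-beta list did not pass against random lists of the same gene body length (a difference of 13.9 points, adjusted simulation p = 0.0595, by permutation). Naming by the nearest start site took in regions outside exons, so 26.15% of protein-coding genes had one, against 12.81%. The lost calls are therefore not an effect of the naming alone.

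Genes of germ cells and of other lineages seldom held an exonic region, but none of these lists passed the test, which could not call lists this small lower. None of 22 genes of primordial germ cell specification held one (upper bound 15.4%; adjusted Fisher's exact p = 0.156), SOX17, PRDM1, NANOS3 and TFAP2C included. Its difference from other genes was -12.8 percentage points, and 5.68 with genes named by the nearest start site (adjusted Fisher's exact p = 0.813). The latter counted regions outside exons as well. ARID5B of this list had a region over the gene body outside exons. Late germ cell genes held 1 in 22, in exon 5 of 8 of MEIOC, a meiosis gene, and DAZL, DDX4 and DMC1 had none (adjusted Fisher's exact p = 0.421). Naive pluripotency genes held 1 in 20, in the 3' UTR of FGF4. Neural ectoderm genes held 1 in 20, in NES, which encodes the intermediate filament nestin, and fibroblast genes 1 in 20, in COL5A1 (adjusted Fisher's exact p = 0.549 for each of these 3 lists). Mesendoderm genes and amnion and trophoblast genes held 0 of 20 each (upper bound 16.8%; adjusted Fisher's exact p = 0.156 for both). At the lowest possible count, 0 of 20 or 0 of 22, the unadjusted Fisher's exact p was 0.099 and 0.102. A list of this size could therefore not be called lower, whatever its count. With genes named by the nearest start site, the amnion and trophoblast list differed from other genes by -26.2 percentage points and passed (adjusted Fisher's exact p = 0.0119). Counting any region over the gene body, the naive, neural, mesendoderm and amnion and trophoblast lists were lower than other genes (adjusted Fisher's exact p from 0.00301 to 0.0222). Gene body length was not held fixed there, and longer genes met a region more often by this measure.

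Polycomb genes held regions in 9 of 34 cases, including CBX2 and BCORL1 (26.5%; adjusted Fisher's exact p = 0.0617), and chromatin remodelers in 8 of 35, including EP400, ARID1A, CHD9 and CHD6 with 2 each (22.9%; adjusted p = 0.139). ARID1B, another remodeler, was not counted because the transcript of its region in exon 20 of 20 did not match the gene table; with such regions placed by position the list did not pass either (12.8 points above other genes, adjusted Fisher's exact p = 0.0664). Both lists, Polycomb and remodelers, passed the threshold with genes named by the nearest start site (adjusted Fisher's exact p of 0.0101 and 0.00601), with any overlap of the gene body (25.7 and 32.7 points above other genes; 0.00478 and 2.64e-04) and with transcript ends and promoters included (0.0454 and 0.0492), and Polycomb genes also with regions up to 2 kb (0.0193). Neither of the first 2 alternatives was restricted to exons or matched on gene body length. Other alternatives went the other way. Against genes with a region, the differences fell from 13.7 to 4.98 points for Polycomb and from 10.1 to -6.07 for remodelers (adjusted Fisher's exact p = 0.863 for both). Against random lists of the same gene body length they were 12.8 and 6.83 points (adjusted p of 0.134 and 0.476 by permutation). Of 15 DNA methylation genes, the dioxygenases TET1, TET2 and TET3 and the hemimethylated-DNA reader UHRF1 held regions and DNMT1, DNMT3A and DNMT3B had none in exons (26.7%; adjusted Fisher's exact p = 0.168). FGF and MAPK genes held them in 7 of 35 cases, including SPRY4 and SPRY1 (adjusted Fisher's exact p = 0.264). SR and hnRNP splicing factors held them in 4 of 30 cases and cell cycle genes in 4 of 39, among them E2F3, MDM2, CDKN1B and CDC25A (adjusted Fisher's exact p = 0.812 for both). None of 19 glycolysis genes, such as ALDOA and ENO1, held one (upper bound 17.7%; adjusted Fisher's exact p = 0.215). Even this lowest possible count gave an unadjusted Fisher's exact p of 0.16, so a list this small could not be called lower.

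By the count of exonic regions, ZNF zinc finger genes and protocadherins stood far above other genes, and ribosomal protein, respiratory chain and other housekeeping families far below. Only gene body length was matched. Exon length, which may set how often a centre falls in an exon, was not held fixed. Of 509 ZNF genes, 298 held an exonic region (58.5%, interval 54.1 to 62.9%), against 11.6% of other genes (odds ratio 10.7, adjusted Fisher's exact p = 1.21e-134). ZNF638 and ZNF778 held 3 each. Of 66 protocadherins, neuronal cell adhesion genes in part clustered on chromosome 5, 42 held one (63.6%, 50.9 to 75.1%; adjusted Fisher's exact p = 7.57e-21), including PCDHA4, PCDHA10 and PCDH1 with 2 each. The test and interval count clustered neighbours as independent genes, which may overstate the evidence. The same holds for ZNF genes and any other family here whose members lie side by side. The region centred in PCDHB10 was 34758 bp wide and ran beyond both ends of that gene. The 45 exonic regions of protocadherins had a median width of 2678 bp and 39 were over 2 kb, so that with regions up to 2 kb alone their difference from other genes was -1.32 percentage points (adjusted Fisher's exact p = 1). SOX genes held regions in 7 of 19 cases, including SOX4, SOX12, SOX11 and SOX2 (36.8%, 16.3 to 61.6%; adjusted Fisher's exact p = 0.0162), 24.1 percentage points above other genes. They did not pass with regions up to 2 kb alone, with genes named by the nearest start site (10.7 points for each), with any overlap of the gene body (17.2 points) or against genes with a region (35.4 points; adjusted Fisher's exact p from 0.145 to 0.437).

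Genes with the symbol pattern of cytosolic ribosomal proteins held regions in 2 of 89 cases, RPL41 and RPL7L1 (2.25%, 0.273 to 7.88%; adjusted Fisher's exact p = 0.00333). All families here follow symbols, so they may take in genes that only share the name of the class, such as RPL7L1. None of 77 mitochondrial ribosomal protein genes held one (upper bound 4.68%; adjusted Fisher's exact p = 2.66e-04), and 2 of 81 respiratory chain and ATP synthase genes did, ATP5IF1 and NDUFV3 (2.47%; adjusted Fisher's exact p = 0.00615). No region was found in exons of 39 proteasome genes (adjusted Fisher's exact p = 0.0162) or 56 translation initiation factor genes (adjusted Fisher's exact p = 0.00288). Core and linker histone genes held regions in 2 of 94 cases (adjusted Fisher's exact p = 0.00179). Families with tissue-restricted expression were low too: olfactory receptors held 1 in 392, OR2A5 (adjusted Fisher's exact p = 4.08e-21), keratins and keratin-associated proteins 0 of 149 (adjusted Fisher's exact p = 2.65e-08) and HOX genes 0 of 39 (adjusted Fisher's exact p = 0.0162). FOX genes held regions in 8 of 52 cases, solute carriers in 38 of 347 and kinesins in 8 of 39, none past the threshold (adjusted Fisher's exact p from 0.21 to 0.566). Solute carriers passed as lower with any overlap of the gene body (a difference of -7.27 percentage points, against -1.89; adjusted Fisher's exact p = 0.00648). That overlap was not matched on gene body length. Against random lists of the same gene body length, the histone genes and HOX genes did not pass (adjusted p of 0.662 and 0.0725 by permutation), and with regions up to 2 kb the HOX and proteasome genes did not (adjusted Fisher's exact p = 0.0664 for both). Olfactory receptors and keratins passed the length matching (adjusted p of 0.0014 and 0.0035 by permutation). Their matched lists held regions in 6.87% and 5.32% of genes, below the 13.1% and 12.9% of other genes. Against genes with a region, which leaves out members without one, the respiratory chain, proteasome, histone and olfactory receptor genes did not pass (adjusted Fisher's exact p from 0.0908 to 1), and the difference of the cytosolic ribosomal proteins turned to 7.6 points on the 4 of 89 members kept, 2 of them with an exonic region (adjusted Fisher's exact p = 1). With genes named by the nearest start site, the mitochondrial ribosomal protein (-2.78 percentage points, against -12.9), translation initiation (-2.94, against -12.8), proteasome (-3.08, against -12.8) and respiratory chain (-7.66, against -10.4) genes did not pass (adjusted Fisher's exact p from 0.215 to 0.928), and the first 3 of these families did not pass with any overlap of the gene body either (-6.85, -3.42 and -12.3 points; adjusted Fisher's exact p from 0.15 to 0.703). Both of these alternatives also counted regions outside exons.

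**Figure D3:**
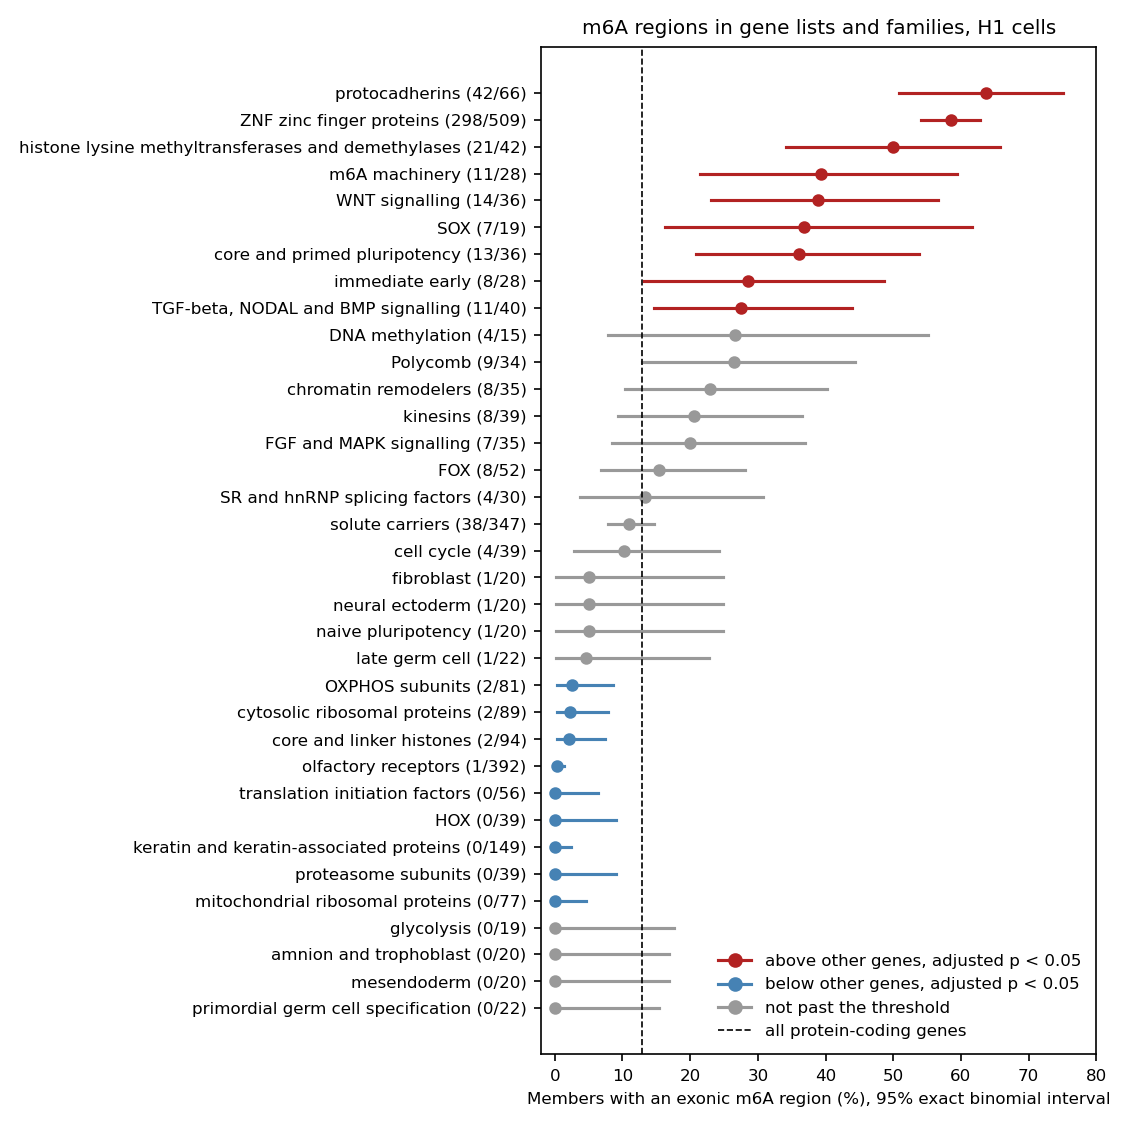
Members with an exonic m6A region (%) for each of 20 gene lists and 15 gene families, with counts of members; points are shares, lines their 95% exact intervals and the dashed line the share of all protein-coding genes (12.8%). Protocadherins (63.6%) and ZNF genes (58.5%) lie highest, and 9 families lie below other genes past the threshold.

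The gene with the nearest start site, which the deposited annotation gives as the gene name, was often not the gene that held the region. The 2 were the same gene for 63.4% of 8466 regions (62.3 to 64.4%), for 97.3% of 74 regions in 5' UTRs and for 41.8% of 696 regions in 3' UTRs (38.1 to 45.6%). The region in the 3' UTR of UHRF1 was given the name KDM4B, and those in the last exon of APC the name SRP19.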

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

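The comparisons of repeat content by region width and their other width limits were chosen after the count of L1 repeats had been seen. L1 is the most abundant family of LINE retrotransposons, and its copies were outside the main comparisons, which concern exons. An L1 label stood at 2215 of the 6282 region centres in introns or between genes (35.3%), which no planned comparison used. L1HS, L1PA2 to L1PA8 and L1PA8A, called young L1 here, made up 1096 of them, with 208 at L1PA7, 188 at L1PA3, 180 at L1PA2, 32 at L1HS and 28 at L1PA8A.

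Intronic regions up to 2 kb had L1 at 38.6% of 2376 centres, against 18.1% of 1323 in intronic regions over 5 kb (Fisher's exact p = 1.38e-39, adjusted p = 8.27e-39). Chance overlap with the repeats of introns would give no such excess if narrow and wide regions sampled like introns. That was not shown, since Alu stood at 6.4% of narrow and 18.4% of wide intronic centres. No narrow region was placed at random in its own intron either, so chance overlap was not settled. Of the L1 centres, young L1 made up 55.6% in narrow and 17.9% in wide intronic regions (Fisher's exact p = 6.94e-27). This goes against narrow and wide intronic regions sampling the L1 subfamilies alike. The L1 make-up of introns themselves was not used, so which of the 2 departs from it is unknown. Older L1 stood at 17.1% of narrow and 14.9% of wide intronic centres (Fisher's exact p = 0.0781, adjusted p = 0.0852 over 12 tests of repeat classes), and at 30.3% and 18.8% of narrow and wide intergenic centres (Fisher's exact p = 0.00405, adjusted p = 0.00608). Between genes the L1 share did not fall steadily with width, at 83.9% of 174 centres from 2 to 3 kb and 68.5% of 54 from 3 to 5 kb, against 59.2% of 943 up to 2 kb. Also open are m6A on RNA that holds L1 copies, and reads of near-identical copies that were placed on 1 of them. Such reads may inflate or move these regions and could not be tested without the reads themselves. No biological explanation was tested.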

How the results depend on the processing

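Alternatives chosen after seeing the data were regions up to 2 kb, overlap with the gene body, exons with transcript ends and promoters, the background of genes with a region, matching on gene body length, unmatched transcripts placed by position, and all variants of the last-exon and L1 tests. Values are differences in percentage points from other genes unless stated. Naming by the nearest start site and overlap with the gene body both counted regions outside exons, and neither was matched on gene body length. The last-exon excess (31.8 to 48.7 points over its alternatives) and the L1 difference by width (18.6 to 27.5 points) kept their direction and their side of the threshold, as did the excess of ZNF genes. A minimum width and merging of close regions changed nothing, since no region was narrower or closer than their limits. Placing unmatched transcripts by position ended or added no call. With genes named by the nearest start site, calls were lost for the m6A machinery (16.7), histone lysine methylation (11.97), WNT (15.55), immediate early (16.7), mitochondrial ribosomal protein (-2.78), respiratory chain (-7.66), proteasome (-3.08), SOX (10.7) and translation initiation (-2.94) genes; 1 list and 5 families were then lower, and 3 results passed that had not. Without olfactory receptors and keratins in the background, immediate early genes lost their call (15.4). With any overlap of the gene body, immediate early (12.7), mitochondrial ribosomal protein (-6.85), proteasome (-12.3), SOX (17.2) and translation initiation (-3.42) genes lost theirs, 4 lists were lower and 7 results passed that had not. With transcript ends and promoters, proteasome genes lost theirs (-11.85) and 2 results passed that had not. With regions up to 2 kb, immediate early (7.46), proteasome (-10.4), HOX (-10.4) and SOX (10.7) genes lost theirs, protocadherins turned to -1.32 because their regions are mostly wider, 1 family was higher, 1 list passed that had not, and introns held 38.2% of centres, coding exons 23.7% and 3' UTRs 9.635%. Against genes with a region, a smaller background that leaves out members without one, calls were lost for pluripotency (22.7), the m6A machinery (31), WNT (27.7), TGF-beta (7.62), immediate early (24.3), respiratory chain (-24.3), proteasome (-42.5), histone (-9.08), olfactory receptor (-25.8) and SOX (35.4) genes, cytosolic ribosomal proteins turned to 7.6 on the 4 of 89 members that this background keeps, 2 of them with an exonic region, and 1 list was higher and 2 families lower. Against lists matched on gene body length, TGF-beta (13.9), histone (-1.65) and HOX (-9.775) genes lost theirs. Apart from the smaller background and the wide protocadherin regions, the cause was not tested. No paired analysis was possible because the deposited set holds no value per library; for the same reason no replicate was left out. Variants of motif, stop codon window, exon length, exon overlap, longest transcript, exonic length and peak score, set out before the data were examined, were not run. Depth, which limits which regions could be called, was unknown.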

Other observations

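The tests of regions over 5 kb and over 100 kb were chosen after the widths had been seen, and the rule for related genes at the ends of regions over 100 kb was tightened after a first count of 14. On chromosome X, L1 stood at 66.8% of 208 narrow intronic and intergenic centres, against 42.9% of 3098 on the autosomes (Fisher's exact p = 2.64e-11). Intronic and intergenic centres were pooled here. The L1 content of these chromosomes was not held fixed, so the difference may be one of the genome alone. HERVH-int, an endogenous retrovirus transcribed in human embryonic stem cells, stood at 4 intronic or intergenic centres, its LTR7 promoter at 1 and SVA elements at 17. Centres in exons, promoters and transcript ends carried no repeat label, so elements there were not counted. Alu elements, the most numerous SINE family, went the other way from L1, at 6.4% of narrow and 18.4% of wide intronic centres (Fisher's exact p = 3.06e-28, adjusted p = 1.22e-27 over 12 tests of repeat classes).

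Intronic regions over 5 kb numbered 1323. L1 stood at 18.1% of their centres and at 38.6% of those up to 2 kb, which leaves chains of signal from L1 copies open, since a region chained from several copies need not have one at its midpoint. Of the 1318 with a host gene body, 94.1% (1240) had both ends inside the host gene, where random placement of the same widths in the same genes gave a median of 78% and an upper limit, over the central 95% of placements, of 79.8%. This goes with fragments whose ends lie in exons on either side of a spliced intron, and it is also what signal from unspliced RNA bounded by the gene would give, so these may not be separated by this test. No biological explanation was tested.

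Of the 73 regions over 100 kb, 10 had different genes of 1 symbol stem by their ends, where random pairings of left and right ends gave a median of 0 and an upper limit of 2 over the central 95% of pairings. NANOG and its pseudogene NANOGP1, NAIP and NAIPP4, and NPIPB3 and NPIPB4 were such pairs. Read pairs split between paralogs may account for these, but related genes also lie in clusters, which random pairing does not hold fixed, so that clustering stays open. A single gene lay by both ends of 18 others, and the rest were not accounted for. No biological explanation was tested.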
